A study of Homo sapiens with 4 samples.

How the data were processed

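Total RNA of MCF-7 cells was sequenced 2 days after transfection with control or DAXX siRNA, in medium with 10% serum, and libraries were built from 1 µg of RNA by standard Illumina protocols, per the labels' protocols. The labels do not say whether the libraries kept strand or were selected for poly(A) RNA. The submitters' processing notes name FastQC 0.11.5, Trimmomatic 0.38, kallisto 0.44.0, DESeq2 without a version, and the GRCh38 build, with no role or order. Kallisto estimates how reads that match several transcripts are divided among them, so genes with near-identical copies are uncertain. Only some of them are marked as such below. The annotation release used by the authors is not given in the sources used here.

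Both deposited tables cover all 4 libraries and 23362 Ensembl genes. The first holds a read signal, normalized counts per gene that the authors deposited after scaling between libraries, per its name in the series. The second holds FPKM values that the authors deposited for the same genes. In all genes above 0 the ratio of the tables was the same in every library within 0.01 percent, so the FPKM table is the first table divided by a length per gene and adds no independent measurement. Columns were matched to libraries by the number in each library's title, and 0 columns matched no sample. Median-of-ratios factors recomputed from genes above 0 in all 4 libraries were 1.01 in each library, so the deposited counts were already on that scale. Most low values, 76.5% to 81.2% by library, fell on whole-number steps within a tolerance of 0.1 step. The rest did not, so whole reads were not recovered for all genes and no count model was fitted. No gene above 0 had identical values in both libraries of a group.

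Gene symbols came from a table of identifiers, which named 23236 of the genes. Coordinates, gene types, GC content and transcript lengths came from GENCODE 29 (Ensembl 94, GRCh38), which held 23350 of the genes, 17549 of them protein-coding. Few long non-coding RNA genes are among the genes used here, so most of that class was not analysed here.

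Genes with a normalized count of at least 10 in at least 2 libraries were kept (16160 genes), and log2(normalized count + 1) was fitted with limma 3.58.1 in R 4.3.3, with the group as the only term, an intensity trend and two-sided tests. P-values were adjusted by the Benjamini-Hochberg method over all genes kept, with a threshold of 0.05. Gene lists with at least 5 genes kept were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 29 lists. The 14 lists that passed covered estrogen-induced genes, estrogen-repressed genes, luminal identity, basal and mesenchymal genes, S phase, G2/M, interferon response, immediate early genes, heat shock, the unfolded protein response, glycolysis and hypoxia, mitochondrially encoded RNA, replication-dependent histones and ZNF genes. The other 15 covered H3.3 and PML bodies, heterochromatin silencing, Notch, stem cell genes, p53 targets, apoptosis, NF-kB, cholesterol, oxidative phosphorylation, imprinted genes, germline genes, ribosomal proteins, and markers of fibroblasts, immune cells and endothelium. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared tables and plots.

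The gene lists were written by hand, except ribosomal protein and ZNF genes, which were picked by symbol, and they name no published source. The lists, the test, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names DAXX, the 5 study genes, the 10 largest rises and 10 largest falls among named protein-coding or long non-coding genes past the threshold with a mean of at least 50 in the higher group and no overlap between groups, up to 4 genes per list that passed, and up to 3 per other list. Genes named outside the rule are marked as such.

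The alternatives were pseudocounts of 0.5 and 5, no filter, a filter of 50, median-of-ratios rescaling, quantile normalization, the FPKM table as log2(FPKM + 0.1) with a minimum of 0.5, limma without its trend or with robust estimation, the replicate number as a block, each library left out, thresholds of 0.1 or at least 2-fold, and for lists an estimated correlation and fry. Removal of each library's trend on GC content or transcript length was added after seeing the data. The list test with an estimated correlation has 2 residual degrees of freedom here, so it has little power. On simulated libraries with the real genes' means and spread and 200 genes changed among 16160, the fit recovered 26% of 100 genes changed by 1 log2 unit and 51% of 100 changed by 2, with 1 false call. In the data 7217 genes passed, far more than the 200 simulated, so the adjusted threshold was stricter in the simulation. These shares therefore do not measure recovery or false calls in the real comparison. Since the deposited values carry no raw read counts, precision is given only as the spread between libraries.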

Results

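RNA was sequenced from MCF-7 cells, a human breast cancer line that expresses the estrogen receptor, 2 days after transfection with siRNA. There were 4 libraries, 2 from cells given a non-specific control siRNA and 2 from cells given siRNA against DAXX, a chaperone that deposits histone H3.3 together with ATRX and is found in PML nuclear bodies. The comparison asks which transcripts differ when DAXX is depleted. Normalized read counts summed to 30851252 and 31689987 in control replicates 1 and 2, and to 30252877 and 29998931 in DAXX siRNA replicates 1 and 2. These totals follow the authors' scaling between libraries, so the number of reads behind each value is unknown and no counting interval is given. Between 15479 and 15926 genes reached a normalized count of 10 in a library. Across genes, Spearman's rho was 0.987 between the control libraries, 0.993 between the DAXX siRNA libraries and 0.944 to 0.950 between libraries of different groups. The first principal component held 75.6% of the variance and separated the groups. The library titles number the replicates without saying that they came from separate cultures, so the p-values measure only the spread between these 4 libraries, which may be technical.

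DAXX RNA was lower in both libraries that received its siRNA. DAXX (ENSG00000204209, chromosome 6, 33318558 to 33323016 in GRCh38) had normalized counts of 452 and 516 in the control libraries and 145 in each DAXX siRNA library. The group means were 484 ± 44.8 and 145 ± 0.149 (SD, n = 2 each), a 3.34-fold lower level. The log2 fold change was -1.73 (SE 0.16; limma, adjusted p = 0.00131), and it stayed between -1.84 and -1.63 under 16 other settings. Here and below, log2 fold changes are on the log2(normalized count + 1) scale, which understates the change of genes with low counts, levels given as n-fold are ratios of the group means, and values after ± are SDs of 2 libraries.

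Among 5 genes of Notch signalling and stem cell function fixed in advance, SOX2 rose and no other passed the test. SOX2, a transcription factor of pluripotent and neural progenitor cells, went from 180 ± 29.5 in control to 360 ± 30.7 with DAXX siRNA, a log2 fold change of 1.00 (SE 0.19; limma, adjusted p = 0.0105). POU5F1, which encodes OCT4, stood at 43.1 ± 1.497 and 33.0 ± 6.49 (adjusted p = 0.36), and NANOG at 35.4 ± 13.6 and 22.6 ± 8.64 (adjusted p = 0.317). NOTCH4, a Notch receptor, stayed below the minimum for testing, at 3.49 and 1.83 in control and 5.57 and 5.05 with DAXX siRNA. ALDH1A1 was not analysed here. Of the 3 that could be tested, SOX2 also passed when adjusted over the list alone, but its limma adjusted p was 0.0757 without DAXX siRNA replicate 1. Near-identical pseudogenes of POU5F1 and NANOG exist, so their values are uncertain.

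The largest rises included genes of a Wnt ligand, a membrane receptor and an antiviral enzyme. WNT2B, a secreted Wnt ligand (chromosome 1, 112466541 to 112530165), rose from 144 ± 39.3 to 2336 ± 10.3. GPER1, the membrane estrogen receptor (chromosome 7, 1082208 to 1093815), rose from 34.3 ± 15.4 to 510 ± 20.2, and SELENOP, the plasma selenium carrier (chromosome 5, 42799880 to 42887392), from 37.3 ± 8.53 to 537 ± 30.9. The rise of FOXO3, a forkhead transcription factor (chromosome 6, 108559835 to 108684774), was 5.13 in log2 units (SE 0.41; limma, adjusted p = 0.000932), above the other named rises, but 2.91 when its near copy FOXO3B was added, below that of WNT2B at 4.04. On its own FOXO3 ranged from 3.32 to 5.31 over 14 other settings, and WNT2B from 3.76 to 4.32 over 16. The top rank of FOXO3 therefore depends on the setting. FOXO3 was at 6.18 and 7.34 in the control libraries, under the minimum of 10, and at 193 and 378 with DAXX siRNA. Its fold thus rests on low control values. FES, RIMBP3, PLA2R1, OAS2, YBX1 and NOMO1 complete the 10 largest rises, with log2 fold changes from 3.61 to 4.10. That of RIMBP3 was 2.20 with its near copies added. Those of YBX1 and NOMO1 are uncertain, since they were -0.05 and -0.23 with pseudogenes or near copies added. YBX1, a gene used by most cells, was at 9.71 in one control library and listed at 0 in the other, against 46.4 and 65.7 with DAXX siRNA. Without control replicate 1 or 2, the log2 fold changes of YBX1 were 5.81 and 2.39, of PLA2R1 4.99 and 2.65, and of NOMO1 2.61 and 4.62. PLA2R1 did not pass without DAXX siRNA replicate 1 (adjusted p = 0.0578), and YBX1 did not pass with no filter (0.0953) or without the intensity trend (0.0841). Exons of WNT2B overlap ST7L and those of SELENOP overlap CCDC152 on the opposite strand, so reads of these pairs may not be told apart.

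The largest falls included CRYAB, a small heat shock protein (chromosome 11, 111908565 to 111923722), which fell from 534 ± 94.2 to 12.2 ± 1.04. HEG1, a receptor of endothelial junctions (chromosome 3, 124965710 to 125055958), fell from 1322 ± 200 to 43.7 ± 21.5, and WNT7A, a Wnt ligand (chromosome 3, 13816258 to 13880121), from 162 ± 17.01 to 3.67 ± 2.58. TTN, the gene of the giant muscle protein titin (chromosome 2, 178525989 to 178830802), had a log2 fold change of -8.13 (SE 0.44; limma, adjusted p = 0.000512), which was -6.00 with CCDC141, an overlapping gene on the same strand, added. Its values were 403 and 347 in control, and 0.784 and a listed 0 with DAXX siRNA. RLIM, a ubiquitin ligase, was at 405 and 306 in control, and at a listed 0 and 14.5 with DAXX siRNA. Its log2 fold change of -6.49 (SE 1.25) was -4.51 without DAXX siRNA replicate 1 and -8.46 without replicate 2. The secreted factors IL20 and CCL26, the RNA polymerase I subunit gene POLR1A, UGT1A3 and ARL14EPL complete the 10 largest falls, with log2 fold changes from -4.81 to -4.40. Without DAXX siRNA replicate 1 or 2, those of WNT7A were -5.84 and -4.65, of POLR1A -4.14 and -5.48, and of UGT1A3 -6.23 and -2.97. CRYAB exons overlap those of HSPB2 on the opposite strand, and TTN exons those of TTN-AS1, which is not among the genes used here. Reads of these pairs may not be told apart. UGT1A3 shares exons with its neighbours in the UGT1A locus, so its value is uncertain (-2.69 with these added), and it did not pass with no filter (adjusted p = 0.0704) or without the intensity trend (0.0643).

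Of 16160 genes tested, 3830 were higher and 3387 lower with DAXX siRNA (limma with Benjamini-Hochberg adjustment, threshold 0.05), or 44.7% in all. At least 2-fold changes were seen in 1667 higher and 1443 lower genes, and at least 4-fold changes in 334 and 398. Protein-coding genes made up 3643 of the higher and 3197 of the lower genes. In 75.5% of genes tested both DAXX siRNA libraries lay on the same side of both control libraries, where chance alone gives 33.3%. Regardless of sign, the median difference per gene was 0.53 in log2 units between group means, 0.20 between control libraries and 0.14 between DAXX siRNA libraries, while the median signed difference between groups was 0.02. The count of 7217 changed genes fell to 4083 without DAXX siRNA replicate 1 and to 4066 without DAXX siRNA replicate 2.

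**Figure D1:**
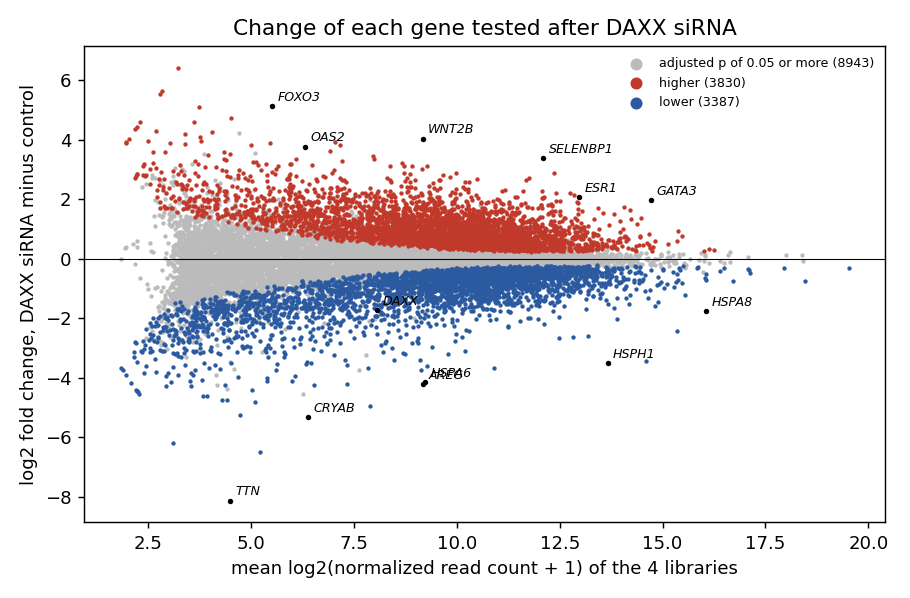
Each dot is 1 of 16160 genes, with the mean log2(normalized count + 1) of the 4 libraries on the x axis and the log2 fold change of DAXX siRNA against control on the y axis. Red genes (3830) were higher and blue genes (3387) lower at a limma adjusted p under 0.05, and labelled examples include DAXX at -1.73 and ESR1 at 2.07.

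Of 25 genes of luminal identity 15 were higher and 5 lower, by the same counts adjusted over the list alone, with a median log2 fold change of 0.66 (camera, adjusted p = 0.0359; adjusted p = 0.345 with an estimated correlation). ESR1, which encodes estrogen receptor alpha (chromosome 6, 151656691 to 152129619), rose 4.19-fold from 3916 ± 82.2 to 16394 ± 382, and GATA3, a luminal transcription factor, 3.89-fold from 13657 ± 2271 to 53060 ± 579. MUC1 and ERBB3 rose by log2 fold changes of 1.78 and 1.52. The luminal list did not pass without control replicate 1 (adjusted p = 0.0549), with a filter of 50 (0.0705), with the FPKM table (0.0638) or without the intensity trend (0.054), in a range of 0.00238 to 0.345 over 18 settings. KRT8 and KRT18, the main luminal keratins and named after their values were seen, stood at 77953 ± 25080 and 97111 ± 6744 in control against 55957 ± 2101 and 88493 ± 86.8 with DAXX siRNA, and did not pass.

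Of 55 genes induced by estrogen, 30 were lower and 10 higher (34 and 11 adjusted over the list alone), with a median log2 fold change of -0.70 (camera, adjusted p = 4.36e-05; adjusted p = 0.28 with an estimated correlation). AREG, an EGF receptor ligand, fell from 2488 ± 19.3 to 134 ± 21.2, FHL2 from 2183 ± 269 to 178 ± 1.83, the carbonic anhydrase gene CA12 from 14381 ± 114 to 2279 ± 290, and the receptor cofactor gene GREB1 from 9479 ± 257 to 2781 ± 6.10. PGR and TFF1, classical estrogen-induced genes named after their values were seen, had log2 fold changes of -1.65 and -0.35 (adjusted p = 0.00435 and 0.0121). Among 30 genes repressed by estrogen, 19 were higher and 7 lower, the same counts adjusted over the list alone, with a median of 1.17 (camera, adjusted p = 0.00449; adjusted p = 0.283 with an estimated correlation). PIK3IP1, an inhibitor of PI3 kinase, rose from 132 ± 1.51 to 1238 ± 25.8, TGFB3 from 162 ± 22.7 to 1413 ± 27.4, the receptor tyrosine kinase gene ERBB2 from 4851 ± 116 to 14706 ± 697, and CCNG2 2.89-fold. Other lists held 13 of the induced and 8 of the repressed genes.

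Basal and mesenchymal genes were lower as a list, 12 of 30 lower and 3 higher, by the same counts adjusted over the list alone, with a median of -0.52 (camera, adjusted p = 0.00449; adjusted p = 0.283 with an estimated correlation). KRT17, a basal keratin, fell from 403 ± 22.3 to 20.4 ± 2.22, TGFBI from 2159 ± 248 to 448 ± 8.75 and the caveolin gene CAV1 from 1526 ± 60.6 to 537 ± 24.5. Markers of other cell types were also tested. Of 7 endothelial markers 4 were lower and 1 higher, and the list did not pass (camera, adjusted p = 0.299). ERG fell from 817 ± 5.83 to 311 ± 60.7 and PECAM1 from 75.7 ± 16.03 to 9.66 ± 5.44, while EMCN rose from 130 ± 1.496 to 313 ± 11.7. Of 7 fibroblast markers COL6A3 was the one past the threshold over all genes (adjusted p = 0.0283) and none passed adjusted over the list alone (camera, adjusted p = 0.429). It did not pass without any one of the 4 libraries (adjusted p from 0.0561 to 0.124), while COL3A1 passed without control replicate 1 (0.0103 in place of 0.0627) and FBN1 likewise (0.0256 in place of 0.0769). None of the 5 genes tested in the immune list, which includes the globin gene HBA1, passed (camera, adjusted p = 0.862). That list's median of 0.04 and mean of -0.09 differed in sign.

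Of 57 interferon response genes 34 were higher and 2 lower (36 and 3 adjusted over the list alone), with a median log2 fold change of 0.99 (camera, adjusted p = 1.15e-06; adjusted p = 0.28 with an estimated correlation). OAS2, a double-stranded RNA sensor, went from 21.1 ± 6.58 to 303 ± 109, IRF9, a subunit of the interferon transcription complex, from 151 ± 3.10 to 667 ± 36.7, IFITM3, a restriction factor of viral entry, from 1055 ± 191 to 3633 ± 168, and SP110 from 58.0 ± 2.60 to 370 ± 48.7. NF-kB and inflammatory genes went both ways, with 9 of 32 higher and 9 lower, also when adjusted over the list alone (camera, adjusted p = 0.78). NFKBIA, the NF-kB inhibitor, rose from 944 ± 15.5 to 2061 ± 72.8 and TNFAIP2 fell from 695 ± 41.0 to 152 ± 18.6.

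Of 27 heat shock genes 19 were lower and 3 higher (20 and 4 adjusted over the list alone), with a median of -1.17, the lowest of the 29 lists (camera, adjusted p = 9.26e-07; adjusted p = 0.3 with an estimated correlation). HSPH1, an HSP110 chaperone, fell 11.4-fold from 43940 ± 3795 to 3853 ± 155, and the stress-inducible HSPA6 fell 17.9-fold from 2525 ± 135 to 141 ± 4.70. DNAJB1, a co-chaperone, fell from 30999 ± 1297 to 7555 ± 327, and HSPB8 from 7118 ± 120 to 2356 ± 14.8. HSF1, the transcription factor that drives heat shock genes and named after its values were seen, was among the higher genes, at 820 ± 89.2 and 1253 ± 42.0. Chaperone genes of this list with many pseudogenes, HSPA8, HSPD1, HSPE1 and HSP90AA1 among them, have uncertain absolute levels.

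Unfolded protein response genes were also lower, 25 of 38 lower and 6 higher (26 and 7 adjusted over the list alone), with a median of -0.67 (camera, adjusted p = 0.000118; adjusted p = 0.28 with an estimated correlation). HSPA5, the chaperone BiP of the endoplasmic reticulum, fell from 72289 ± 3205 to 31264 ± 718, PSAT1, an enzyme of serine synthesis, from 1516 ± 19.7 to 456 ± 19.1, and PPP1R15A from 11871 ± 543 to 5587 ± 166. Immediate early genes, which respond within minutes to growth factors and to handling of cells, were lower in 17 of 34 cases and higher in 2 (17 and 3 adjusted over the list alone). Their median was -0.63 (camera, adjusted p = 0.000155; adjusted p = 0.36 with an estimated correlation). FOSB fell from 2941 ± 197 to 541 ± 2.86, EGR1 from 5389 ± 447 to 1091 ± 34.5, and DUSP1 from 2877 ± 95.9 to 698 ± 5.73. Lists overlap, since others held 6 of the unfolded protein response genes, 9 of the immediate early genes and 3 of the heat shock genes.

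**Figure D2:**
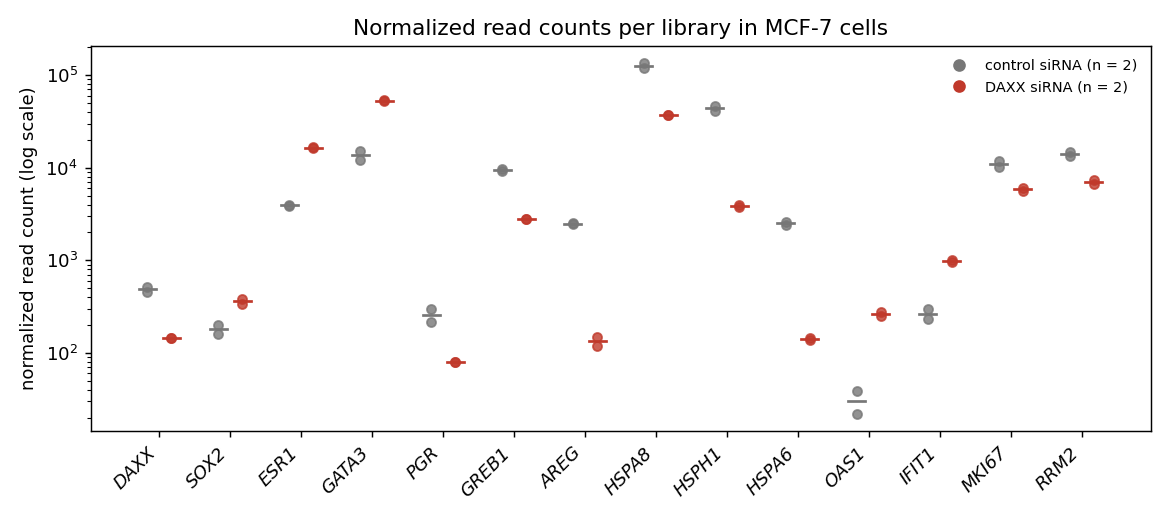
Normalized read counts on a log axis for 14 genes, with each dot a library, each bar the mean of 2 libraries, control siRNA in grey and DAXX siRNA in red. DAXX falls from 452 and 516 to 145 in each library, ESR1 rises from a mean of 3916 to 16394, and HSPH1 falls from 43940 to 3853.

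Of 60 S phase and E2F target genes 29 were lower and 1 higher (30 and 1 adjusted over the list alone), with a median log2 fold change of -0.35 (camera, adjusted p = 2.21e-06; adjusted p = 0.283 with an estimated correlation). ATAD2, a chromatin regulator, fell from 9255 ± 127 to 3494 ± 9.95, CDC25A, a phosphatase of the cell cycle, from 1371 ± 132 to 492 ± 15.3, and ORC6, a subunit of the origin recognition complex, from 2523 ± 168 to 918 ± 65.4. Of 66 G2/M and mitosis genes 32 were lower and 3 higher (35 and 3 adjusted over the list alone), with a median of -0.47 (camera, adjusted p = 4.6e-07; adjusted p = 0.345 with an estimated correlation). ANLN, a protein of the contractile ring, fell from 6061 ± 860 to 1887 ± 235, and HJURP, the chaperone of centromeric CENP-A, from 2100 ± 119 to 852 ± 64.6. Among p53 targets 21 of 52 were higher and 12 lower, also adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.0918, and 0.042 without control replicate 1). DDB2, a DNA repair factor, rose from 1547 ± 114 to 4479 ± 59.2 and KITLG from 2650 ± 27.3 to 7012 ± 326. Apoptosis regulators went both ways, 10 of 42 higher and 11 lower, the same adjusted over the list alone (camera, adjusted p = 0.697), with BAK1 and BMF, which promote cell death, at log2 fold changes of 1.67 and 2.24. Named after their values were seen, PMAIP1 and TNFRSF10A, which also promote it, fell (-1.73 and -1.38), and BCL2 and BCL2L1, which oppose it, rose (1.33 and 0.92).

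Of 42 glycolysis and hypoxia genes 22 were lower and 6 higher, the same adjusted over the list alone, with a median of -0.41 (camera, adjusted p = 0.00661; adjusted p = 0.345 with an estimated correlation). SLC2A1, the glucose transporter GLUT1, fell from 10207 ± 9.81 to 5815 ± 34.6, and PGAM1, a glycolytic enzyme with many pseudogenes, from 24168 ± 700 to 12779 ± 64.4. Of 13 mitochondrially encoded RNAs 7 were lower and none higher, also adjusted over the list alone, with a median of -0.30 (camera, adjusted p = 0.0116; adjusted p = 0.592 with an estimated correlation). MT-ND4L and MT-ND4, subunits of complex I, fell by 1.06 and 0.75 in log2 units. These RNAs took 9.02% and 9.57% of the normalized counts in control libraries and 8.02% and 7.94% with DAXX siRNA. The list did not pass with quantile normalization (adjusted p = 0.482) or without DAXX siRNA replicate 1 (0.0581) or 2 (0.0796), in a range of 8.52e-05 to 0.592 over 18 settings, and MT-ND4 did not pass without either (0.0596 and 0.0585). Nuclear genes of oxidative phosphorylation did not pass as a list, 11 of 65 lower and 5 higher (9 and 5 adjusted over the list alone; camera, adjusted p = 0.32, and 0.0404 without control replicate 1), and CYCS, cytochrome c, fell from 8447 ± 367 to 3081 ± 343 while NDUFC1 rose from 986 ± 90.3 to 2603 ± 268. Cholesterol synthesis genes did not pass either, 12 of 34 lower and 7 higher, also adjusted over the list alone (camera, adjusted p = 0.16), with MSMO1 lower by -1.71 and TM7SF2 higher by 1.86 in log2 units.

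The list of H3.3 deposition and PML body genes had 10 of 32 higher and 3 lower, also adjusted over the list alone. It holds genes such as HIRA and CENPA and is not limited to partners of DAXX. The list did not pass (camera, adjusted p = 0.0957, and 0.0316 with no filter). HIPK1, a kinase found in PML bodies, rose from 5930 ± 101 to 12426 ± 133, and MDM2, the ubiquitin ligase of p53, from 4671 ± 497 to 9710 ± 257. Genes of heterochromatin silencing went both ways, 7 of 30 higher and 9 lower (11 and 10 adjusted over the list alone; camera, adjusted p = 0.804). TASOR, a subunit of the HUSH silencing complex, rose from 838 ± 1.85 to 2099 ± 144 and the HP1 gene CBX3 fell from 15456 ± 552 to 10383 ± 244. Imprinted genes had 5 of 19 lower and none higher, also adjusted over the list alone (camera, adjusted p = 0.16), PEG10 and MEST being lower with log2 fold changes of -1.03 and -0.70. Germline and cancer-testis genes had 2 of 16 higher and 2 lower (1 and 2 adjusted over the list alone; camera, adjusted p = 0.925), with SYCP2 of the synaptonemal complex rising from 317 ± 121 to 1584 ± 152, TDRD1 falling from 276 ± 8.63 to 119 ± 0.150 and TEX14 from 1063 ± 34.9 to 537 ± 163. TEX14 did not pass with no filter (adjusted p = 0.0506) or without the intensity trend (0.0533). The list's median of -0.12 and mean of 0.14 differed in sign and camera's direction was reversed without control replicate 2 (0.911).

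Replication-dependent histone genes rose as a list, 16 of 36 higher and 3 lower (16 and 4 adjusted over the list alone), with a median of 0.43 (camera, adjusted p = 0.0169; adjusted p = 0.592 with an estimated correlation; 0.0638 with the FPKM table, in a range of 0.00131 to 0.592 over 18 settings). H2BC5 rose from 436 ± 44.0 to 1923 ± 19.2, H2AC6 from 1165 ± 3.55 to 3376 ± 159 and H1-2 from 1060 ± 43.3 to 2935 ± 97.6. These genes are near copies of each other and mostly lack poly(A) tails, so single values are uncertain. Zinc finger genes of the ZNF family had 149 of 463 higher and 61 lower, also adjusted over the list alone, with a median of 0.24 (camera, adjusted p = 0.0404; adjusted p = 0.28 with an estimated correlation). ZNF468 rose from 383 ± 53.2 to 1499 ± 43.6 and ZNF517 from 148 ± 17.3 to 568 ± 39.3. The ZNF list did not pass with quantile normalization (adjusted p = 0.182) or without control replicate 1 (0.0549) or 2 (0.0868), in a range of 0.00339 to 0.28 over 18 settings.

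Notch pathway genes did not pass as a list, 13 of 35 higher and 5 lower (15 and 5 adjusted over the list alone; camera, adjusted p = 0.107), although ADAM10, a protease that cleaves Notch receptors, rose from 2671 ± 204 to 4928 ± 89.7 and the coactivator gene MAML3 from 309 ± 10.3 to 830 ± 66.1. Pluripotency and breast stem cell genes did not pass either, 2 of 19 higher and 4 lower, the same adjusted over the list alone (camera, adjusted p = 0.309). SALL4, a pluripotency factor, rose from 170 ± 10.3 to 1054 ± 52.2, while ABCG2, a drug efflux pump, fell from 9622 ± 552 to 4850 ± 95.5 and MYC from 2876 ± 320 to 1208 ± 70.5. Cytosolic ribosomal protein genes had 11 of 85 higher and 8 lower (4 and 1 adjusted over the list alone; camera, adjusted p = 0.804), with a median of -0.01 and a mean of 0.00. Camera put this list lower without control replicate 1 (adjusted p = 0.0335) but higher with quantile normalization (0.00492), without control replicate 2 (0.268) and without DAXX siRNA replicate 2 (0.771), in a range of 0.00492 to 0.947 over 18 settings.

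Over 29 lists, camera with its preset correlation of 0.01 called 5 higher and 9 lower, and with a correlation estimated from the residuals it called none, the lowest adjusted p being 0.28. With 4 libraries that estimate, and the test that uses it, rest on 2 residual degrees of freedom. The estimates for estrogen-induced genes (-0.0146) and interferon response genes (0.0014) lay below 0.01, yet both lists lost their calls. Other estimates lay above it, such as that of G2/M genes (0.1311). A call lost this way can come from the few degrees of freedom alone, so it does not decide on the list. Fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes, called 17 of the 29 lists.

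**Figure D3:**
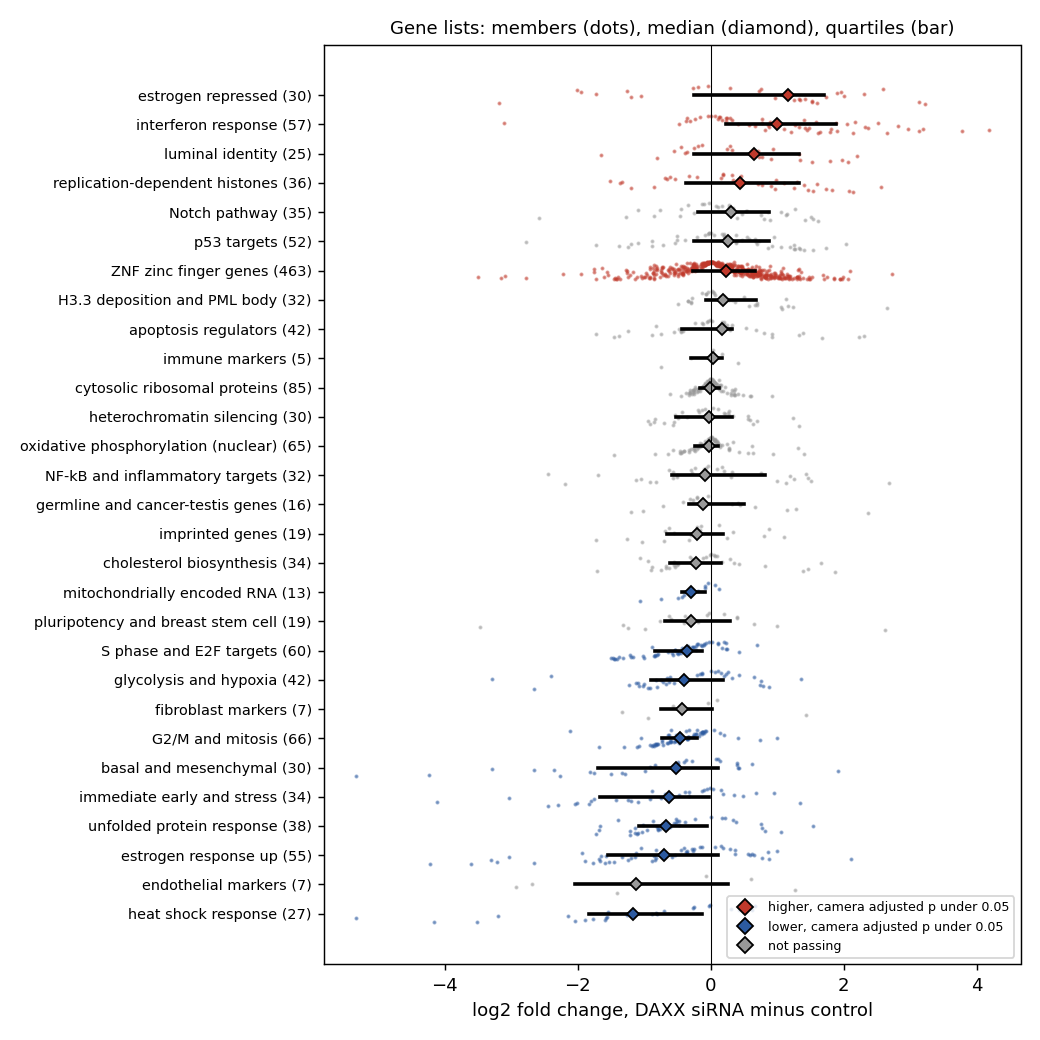
Log2 fold changes of DAXX siRNA against control for the genes of 29 lists (dots, with the number tested in parentheses), with the median (diamond) and the quartiles (black bar), in red or blue where camera called the list higher or lower and in grey where it did not. Medians run from -1.17 for heat shock genes to 1.17 for genes repressed by estrogen, and no list passed with an estimated correlation.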

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

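Removal of GC content and length trends was chosen only after the result was seen, and the other settings were fixed earlier. The log2 fold change of DAXX kept its direction and its call under all 16 settings (-1.84 to -1.63, highest adjusted p 0.0125). The count of changed genes was 7217. Leaving out a library in turn (4083 without DAXX siRNA replicate 1, 4066 without replicate 2) gave 4066 to 7767 changed genes, 1971 to 4396 higher and 2095 to 3371 lower, with the lone library of a group assumed to vary like the others. The lowest counts came without either DAXX siRNA library, where the spread between libraries rests on the control pair alone. The median difference per gene, regardless of sign, was 0.20 in log2 units between control libraries and 0.14 between DAXX siRNA libraries. A wider spread gives fewer calls, and no other cause was tested. The addition of an at least 2-fold change left 3110 genes, 1667 higher and 1443 lower, which follows from the threshold itself. Other settings gave 5885 (limma without trend) to 8764 genes (threshold of 0.1), and between 49.6% (quantile normalization) and 54.5% (GC trend removed) of the changed genes were higher.

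The replicate numbers give no pairing by the labels, and same-numbered libraries deviated together with r = 0.0331 across genes. With the number as a replicate block 7446 genes changed, 6840 of them shared with the 7217, and no gene list changed its call, while COL3A1 passed with the block (adjusted p = 0.043).

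For gene lists, the estimated correlation left 0 of 14 calls, with 2 residual degrees of freedom and so little power. Direction reversed, with adjusted p in parentheses, for germline genes with no filter (0.883), with the FPKM table (0.931), without control replicate 2 (0.911, and up to 0.952 over the libraries left out) and with fry (0.526), for immune markers with quantile normalization (0.869), for heterochromatin genes with the GC trend removed (0.944), and for ribosomal proteins with quantile normalization (0.00492), the GC trend removed (0.561), fry (0.928), and without control replicate 2 (0.268) or DAXX siRNA replicate 2 (0.771; 0.0335 and lower without control replicate 1). The cause was not tested. In all, list tests gave 469 unchanged calls, 26 lost, 12 gained and 11 reversed directions, and single named genes 1843 unchanged, 20 lost and 5 gained. Gained list calls included p53 targets (0.0262), H3.3 and PML bodies (0.0316) and Notch (0.0316) with no filter, and p53 targets (0.00617) with fry. The unknown depth limits all statements on genes near the minimum of 10.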

Other observations

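The gene lists of this part were written by hand only after the result was seen. Some members of the NRF2, YAP and TEAD, FOXO, rRNA processing and lysosome lists had been looked at before. The p-value of such a full list is therefore not an independent test. Also chosen after the result were the tests on YBX1 and NOMO1, on the 4 other genes with a copy, and on immediate early genes. The same holds for the test on FOXO targets and the removal of GC and length trends. The limits for the tests of chromosome windows, of shared reads over 20 genes and of transcript number were set before these tests were run. That need not mean before the result was seen.

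Target genes of NRF2, the regulator of the antioxidant response, were lower in 26 of 27 cases and higher in none, with a median log2 fold change of -1.23 (camera, adjusted p = 1.18e-12 over 8 added lists; adjusted p = 0.153 with an estimated correlation). Of the 23 that had not been looked at before, 22 were lower, with a median of -0.82 (camera, adjusted p = 3.58e-10; adjusted p = 0.221 with an estimated correlation). HMOX1, which degrades heme, fell from 80854 ± 739 to 7482 ± 45.8, AKR1C2, an aldo-keto reductase with close paralogs, from 22897 ± 2263 to 3770 ± 59.3, TXNRD1, thioredoxin reductase, from 40258 ± 1664 to 16112 ± 511, and G6PD, which makes NADPH, from 50193 ± 4875 to 18425 ± 811 (SD, n = 2 each). Target genes of YAP and TEAD were lower in 18 of 26 cases and higher in 1, with a median of -0.85 (camera, adjusted p = 1.07e-06; adjusted p = 0.153 with an estimated correlation). Of the 20 that had not been looked at before, 13 were lower and 1 higher, with a median of -0.61 (camera, adjusted p = 0.000182; adjusted p = 0.221 with an estimated correlation). ANKRD1 and CCN2, both looked at before, and TEAD1, which was not, were lower. ANKRD1 fell from 1155 ± 75.4 to 108 ± 11.9, CCN2 from 266 ± 0.221 to 14.4 ± 1.49, and TEAD1 from 3198 ± 306 to 1222 ± 19.9.

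Genes of rRNA processing and tRNA charging were tested as lists beside the cytosolic ribosomal protein genes, which did not pass (11 of 85 higher, 8 lower, median -0.01; camera, adjusted p = 0.804, but 0.00492 and higher with quantile normalization). In the rRNA processing and nucleolus list 29 of 50 were lower and 2 higher, with a median of -0.47 (camera, adjusted p = 1.16e-07; adjusted p = 0.205 with an estimated correlation), DDX21 falling from 16158 ± 227 to 5029 ± 220 and NOP56 from 7017 ± 690 to 2677 ± 7.43. Aminoacyl-tRNA synthetases had 14 of 20 lower and 2 higher (median -0.62; camera, adjusted p = 0.000106; adjusted p = 0.205 with an estimated correlation), none of them looked at before, IARS1 falling from 18046 ± 1103 to 7157 ± 107. The TRiC chaperonin had 4 of 8 subunits lower and none higher (camera, adjusted p = 0.0203; adjusted p = 0.516 with an estimated correlation), and the proteasome 13 of 31 lower and 4 higher (camera, adjusted p = 0.00791; adjusted p = 0.604 with an estimated correlation). Lysosome genes had 13 of 37 lower and 6 higher and did not pass (camera, adjusted p = 0.101).

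For the change of 44.7% of genes tested, a smooth trend on GC content explained 2.79% of the variance of log2 fold change (limit set at 10%), and 7938 genes changed once each library's trend was removed. A trend on transcript length explained 0.277%, with 7201 genes after removal, and windows of 10 Mb explained 2.72 percentage points more than shuffled genes (4.63% against 1.91%, highest of 1000 shuffles 2.43%), under the 5 points set as the limit. These values argue against GC content, length or a copy number difference between cultures as the whole cause. What lies behind the excess of the windows over shuffled genes was not tested, and neighbouring genes of a family that move together would also add to it. Depletion of DAXX, effects of the siRNA on other transcripts, and a difference in growth between the dishes stay open, since the design puts each of them on the group and none was tested.

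For the largest folds, shared reads are a candidate explanation in part. With pseudogenes, near copies and same-strand overlapping genes added, 2 of the 20 genes had their log2 fold change brought under 0.5 times its size, YBX1 and NOMO1, the larger of their values then being -0.23. Genes that overlap WNT2B, SELENOP, CRYAB and TTN on the opposite strand were not added, although it is unknown whether the libraries kept strand. Those over TTN, TTN-AS1 among them, are absent from the genes used here and could not be added. The 4 others with a copy among the genes used here kept at least 2.20 in size. This argues against reads shared with the added copies as their whole cause, but for TTN opposite-strand reads stay open. Another 14 had no copy there, so for them shared reads stay open. The limit of 2 genes set before the test was therefore too loose. A shift between transcripts of different length was tested by the share of genes at an absolute log2 fold change of 3 or more, which was 2.83% of 741 genes with 1 annotated transcript and 0.684% of 11697 with several, a ratio of 4.14. Since only 2 of the 20 genes have 1 annotated transcript, the test does not reach the others, and for these a shift cannot be told apart from a change in level.

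The fall of heat shock genes was weighed last. With the GC trend removed their median stayed at -1.14 (camera, adjusted p = 8.78e-08; the range over 18 settings was 8.78e-08 to 0.3), which argues against that trend as the cause. A difference in acute stress between the dishes stays open. The 25 immediate early genes in no other list had a median of -0.58, with 12 lower and 1 higher. They are part of the list already seen to be lower, so they add no separate support. A difference in acute stress cannot be told apart from an effect of DAXX depletion, because each group's dishes received 1 siRNA.

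FOXO3 was among the 10 largest rises on its own value (5.13), though not with its near copy FOXO3B added (2.91). A list of FOXO target genes, some of them already seen to be higher, was then tested. Of 36 targets 20 were higher and 6 lower, with a median of 0.61 (camera, adjusted p = 0.000935; adjusted p = 0.153 with an estimated correlation). Of the 25 set apart as not looked at before 12 were higher and 5 lower, with a median of 0.40 (camera, adjusted p = 0.0354; adjusted p = 0.221 with an estimated correlation). Among these, KLF9 (0.28) and BCL2L11 (-0.42) also stood in lists tested earlier, so the set was not wholly unseen. RBL2 rose from 1307 ± 109 to 4647 ± 242 and CAT, catalase, from 605 ± 45.2 to 2065 ± 173, while MAP1LC3B fell from 13404 ± 308 to 8741 ± 194. These values are consistent with higher FOXO activity with DAXX siRNA, which may also follow from other changes in these cells, and RNA levels do not show where the FOXO proteins act.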
